A study of Rattus norvegicus with 34 samples.

How the data were processed

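Gene expression was measured with 34 2-colour PIQOR cDNA arrays of tissues from pregnant Wistar rats and their embryos, in 15 groups of tissue, day and treatment. Vehicle RNA was labelled with Cy3 and RNA of the treated animals with Cy5 on the same array, per the labels. For each array and channel, the deposited file holds the intensity of each spot and of its local background, not background subtracted, per the file headers an export of image quantification with fixed circles. A deposited table of the series holds the log2 ratio of treated over vehicle for each grid position. Set against the spot intensities, its values follow the ratio without background subtraction and without centring. For each fit below that used them, the median of each array was subtracted first.

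Each array held 4 blocks of 256 grid positions, and each probe 4 replicate spots. The spot files name genes in their own way, and 239 probes with a gene name were used. Of these names, 188 matched a gene symbol, 22 a synonym and 5 a full name, while 7 that stand for several genes, 8 of the UGT1 family and 9 without a match were kept as written. The arrays fall into 3 sets by array number, called array batches A, B and C, and 7 of the probes were used in array batch C alone. The batches disagreed on the name at 11 grid positions, and 4 positions were left out for that reason. Across batches, intensities of the same grid position correlated with a Spearman rho from 0.902 to 0.964 over 232 positions, against at most 0.212 for any of 231 shifted grids.

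Intensities were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50) and turned into the log2 ratio of Cy5 over Cy3. Ratios were normalized within each array by global loess, with control, empty and marked spots at weight 0. Replicate spots were then averaged on the log2 scale without the spots that the files mark, namely 766 marked by hand, 4521 dim and 636 uneven, beside 28893 unmarked. A spot counted as above background where its foreground exceeded the local background by more than 2 SD, and a probe where at least a share of 0.5 of its usable spots did. Probes above background in at least 1 channel on at least 2 arrays were tested. Arrays held from 604 to 976 unmarked spots.

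All 34 arrays entered a single limma fit with a mean for each of the 15 groups and a pooled, moderated variance for each gene (prior degrees of freedom 3.38). Contrasts were each group against vehicle, the high minus the low dose of EMD 82571, and the high dose minus retinoic acid, 25 in all, with 15 more between tissues or days. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. Of 18 gene lists fixed in advance, 12 had at least 5 measured genes and were tested with camera against the other genes (preset correlation 0.01, and again with an estimated correlation, which could not be estimated for morphogen signalling), adjusted over the lists of a contrast. Where only 1 of the channels was above background, a fold is given as a bound against the background, and where neither was, no fold is given, nor a value for a difference between doses or compounds that rests on a group with a channel below background on each array.

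Genes were named by a rule. Up to 8 highest and 8 lowest genes past the threshold, with the same sign on each array, were taken for the high dose and retinoic acid, and up to 5 and 5 for the low dose and for the differences. Up to 4 members with the smallest p were taken from each list described, together with a set of genes fixed for their role in retinoid, bone or drug response. Groups, tests, lists, the naming rule and most alternatives were set before the data were examined. Alternatives changed the background correction, the normalization, the filter on dim probes, the arrays in the fit, the handling of array batch and the source of the values. Another subtracted the mean of each gene over the groups, which removes a dye effect shared by all arrays but also part of the treatment effects. Each array was also left out in turn. Added after seeing the data were keeping uneven spots, a random block for the date session in the file headers, limiting the tests to probes above background on each array compared, and testing the tissue and day differences with retinoic acid within array batches.

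The pipeline was tested on simulated data made from the arrays. With 2 arrays, changes of log2 1 were called in 30 of 30 simulated genes and changes of 0.5 in 27 of 30 (93.1% of those with a value). Median estimates were 0.877 and 0.448, and 1 of 179 unchanged genes was called. With 4 arrays, 29 and 30 of 30 were called, with median estimates of 0.936 and 0.445, and 4 unchanged genes were called. The simulated noise had a fixed size and was independent between arrays, without effects of array batch or session. These rates therefore do not carry over to groups whose arrays differ by batch, such as the day-12 embryo with retinoic acid. A list of 10 genes shifted as a set was called by both forms of camera. The relation of the log2 ratio to the maternal liver level was tested by permutation over genes, two-sided.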

Results

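Expression was measured on 34 small 2-colour cDNA arrays, each pairing RNA from treated rats (Cy5) with RNA from vehicle-treated rats (Cy3). The treated animals were pregnant Wistar rats, or their embryos, given EMD 82571, a calcium sensitizer according to the series title, at 50 or 150 mg/kg/day (the low and the high dose below) or retinoic acid, a teratogenic vitamin A derivative. Tissues were whole embryo and maternal liver on gestational day 12, and maternal liver, embryo liver and embryo bone on day 20. The 15 groups held 2 arrays each, except the embryo and maternal liver groups with retinoic acid on day 12, which held 4 each. The series text names 5 control and 5 treated biological replicates, which does not match the number of arrays, and the labels do not say whether the arrays of a group carry RNA of separate animals, pools or technical repeats, or whether groups shared vehicle RNA. If they are technical repeats, the errors and p values below cover technical error only. The retinoic acid dose is 12 mg/kg/day in the dosing protocol and 20 mg in the sample labels, and the titles hold 20, 6 or no number beside RA, without a unit, so no dose is attached to it here. The protocol names dosing on gestational days 6 to 11 and 6 to 17 without saying which groups each window covers.

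In all, 239 probes carried a gene name and could be tested, 7 of them on the arrays of array batch C alone, a chosen set rich in genes of drug metabolism, extracellular matrix, growth factors and development. Median signal over background per array ranged from 1.54 to 4.44 in the vehicle channel and from 1.2 to 5.29 in the treated channel. Between 69.5% and 100% of the probes lay above background, with a median of 93.7%. The number of arrays limits the precision. Ratios of an array correlated with those of its group mates with a mean r across genes of 0.137 to 0.979. Dyes were never swapped, so a gene-specific dye effect is part of each ratio of treated over vehicle. It cancels in the differences between doses or compounds only where it was alike on the arrays compared. Some differences between compounds compare arrays of unlike array batch or session. All adjusted p values come from limma, two-sided, and errors are standard errors. Both rest on a variance pooled over all groups, so they are not the spread of the arrays of 1 group. The unlike array batches of the day-12 embryo with retinoic acid enter that variance and widen the errors of some genes. For the high dose minus retinoic acid in the day-12 embryo, the standard error of Hnf4a was 0.235. It was 0.087 against array batch A alone, in a fit with a mean for each batch.

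The comparisons ask how maternal and embryonic tissues changed with each compound, whether the doses of EMD 82571 differed, and whether the high dose differed from retinoic acid. With retinoic acid, 126 of 235 genes passed the threshold in embryo bone and 115 of 228 in embryo liver, where the high dose of EMD 82571 gave 92 of 238. Limited to probes above background on each array compared, these counts were 84, 78 and 91.

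**Figure D1:**
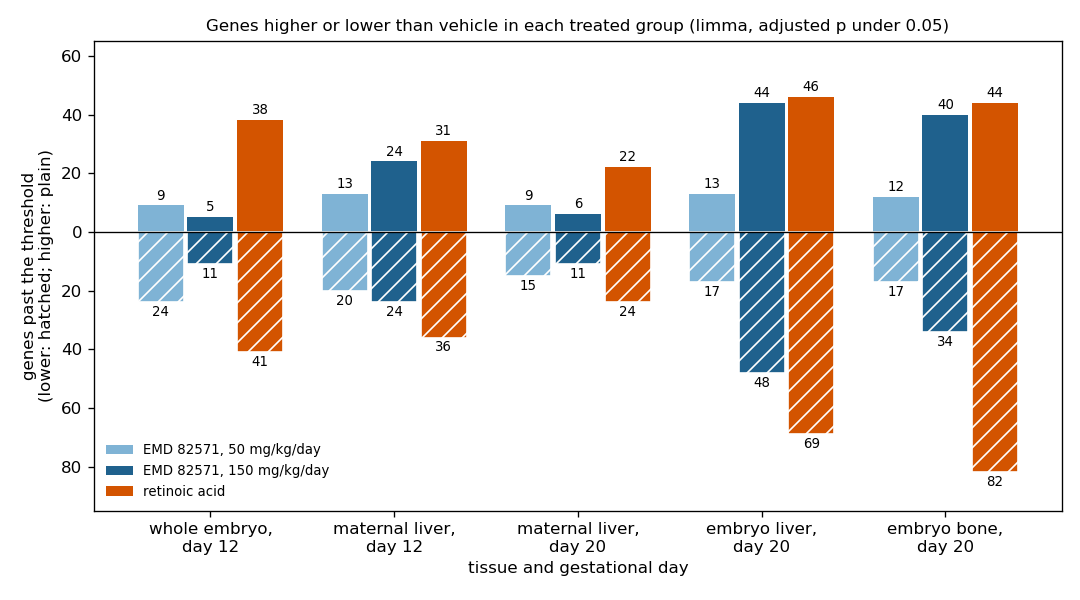
Genes higher (plain bars, upward) and lower (hatched bars, downward) than vehicle in each tissue and treatment, as the number past an adjusted p of 0.05. Counts run from 16 in the day-12 embryo at the high dose of EMD 82571 to 126 in embryo bone with retinoic acid.

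In maternal liver on day 12, the low dose of EMD 82571 raised drug-metabolizing enzymes. CYP2B1/2, the phenobarbital-inducible cytochrome P450 probe, rose 4.29-fold (log2 2.10 ± 0.12, n = 2, adjusted p = 7.14e-11), and Cyp3a23-3a1, a steroid- and drug-oxidizing P450, rose 3.39-fold (1.76 ± 0.11). Ugt2b, a glucuronosyltransferase, rose 2.41-fold (1.27 ± 0.05, adjusted p = 1.03e-12). UGT1A1, which conjugates bilirubin, and Cyp3a18 rose by log2 0.56 and 0.48. Among the genes that fell were Junb, an AP-1 transcription factor (-0.85 ± 0.15), Acta2, smooth muscle actin (-0.64), Col15a1, a basement membrane collagen (-0.57), Ybx3 (-0.56) and Top2a, a topoisomerase of dividing cells (-0.54). Of 19 measured members of the phase I list (phase I xenobiotic metabolism and its receptors), 4 rose and none fell, including CYP2A1/2 (0.39), and 4 rose and 1 fell when adjusted over the list alone. Of 9 members of the phase II list (phase II conjugation, transport and antioxidant defence), 2 rose, also when adjusted over the list alone, while Nat1 (0.19) and UGT1A6 (0.17) did not pass. Both lists moved up against the other genes (camera adjusted p = 0.0028 and 0.02), and both calls held with an estimated correlation (adjusted p = 0.0343 each). In all, 33 of 231 genes passed, 13 higher and 20 lower. The count was 15 without replicate 1 and 16 without replicate 2, when Acta2, Col15a1 and CYP2A1/2 no longer passed, nor did Top2a without replicate 2.

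At the high dose, CYP2B1/2 and Cyp3a23-3a1 rose further in maternal liver on day 12. CYP2B1/2 was up 38.4-fold (5.26 ± 0.12, n = 2, adjusted p = 1.55e-17) and Cyp3a23-3a1 7.53-fold (2.91 ± 0.11, adjusted p = 1.07e-15). UGT1A2 (0.89), UGT1A1 (0.86), Cyp3a18 (0.75) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (0.82 ± 0.08), rose as well, with Lama3, a laminin chain (0.60), and the growth factor Fgf1 (0.55). Junb fell 2.35-fold (-1.23 ± 0.15), Egf, the ligand of the epidermal growth factor receptor, fell 1.85-fold (-0.89 ± 0.04), and Cyp2e1, an ethanol-oxidizing P450, fell 1.55-fold (-0.64 ± 0.14). The proteoglycan Dcn (-0.63), the nuclear receptor Pparg (-0.60), the hepatic transcription factors Foxa2 (-0.49) and Foxa3 (-0.37) and the collagen Col5a2 (-0.45) were lower. Of the 19 phase I genes, 6 rose and 2 fell, or 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0438), a call lost at adjusted p = 0.237 with an estimated correlation. Of 8 genes of hepatocyte function, 1 rose and 3 fell, and of 21 growth factors and receptors 1 rose and 4 fell, with the same numbers when each was adjusted over the list alone and neither list called, and the hepatocyte list had a median of 0.02 and a mean of 0.03 against a test direction of down. In all, 48 of 232 genes passed, 24 in each direction. The count was 18 without either array, when Dcn, Pparg and Foxa3 no longer passed, nor did Cyp2e1 and Foxa2 without replicate 1, and the phase I list had an adjusted p of 0.0518 without replicate 2.

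With retinoic acid, Ugt2b and Cyp7a1 rose in maternal liver on day 12, as each did at a dose of EMD 82571. Ugt2b rose 2.35-fold (1.23 ± 0.04, n = 4, adjusted p = 3.53e-15), Cyp7a1 rose 1.85-fold (0.88 ± 0.06) and Cyp3a9 rose 1.6-fold (0.68 ± 0.07). Cyp2e1 (0.40), the growth factor receptor Egfr (0.40), the integrin Itga9 (0.39), Tgfb2 (0.35) and Ugt2b15 (0.33, with 0.56 in array batch B and 0.11, not passing, in array batch A) rose less. Top2a fell 1.57-fold (-0.65 ± 0.08), Junb fell 1.54-fold (-0.63 ± 0.10), and Ybx3 (-0.54), Foxa2 (-0.39), Jun (-0.38), Egf (-0.31) and the ribosomal protein gene Rps3 (-0.29) were lower. The size differed between array batches A and B for Jun (-0.17 and -0.60), Top2a (-0.93 and -0.37), Ybx3 (-0.35 and -0.73), Rps3 (-0.42 and -0.15) and Itga9 (0.52 and 0.26), each passing in both. Rarb, a retinoic acid receptor that retinoic acid itself induces, rose by log2 0.17 ± 0.05. CYP2B1/2 (0.14) and Cyp3a23-3a1 (0.07) did not pass, and their arrays split by array batch, with CYP2B1/2 at -0.37 in array batch B alone and Cyp3a23-3a1 at -0.21 in array batch A alone. Of the 19 phase I genes, 7 rose and 1 fell, and of 10 genes of TGF-beta and BMP signalling 4 rose and 2 fell, both also when adjusted over the list alone and without a list call. In all, 67 of 232 genes passed, 31 higher and 36 lower. Of the 126 probes above background in both channels on each array 47 passed, 27 higher and 20 lower. Array batch A alone gave 73 genes and array batch B alone 96, and Rarb did not pass without replicate 3 or without replicate 4.

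The difference between the doses was itself tested in maternal liver on day 12. CYP2B1/2 was 8.96-fold higher at the high than at the low dose (3.16 on the log2 scale), and Cyp3a23-3a1 (1.15), Lama3 (0.83), Acta2 (0.83) and UGT1A2 (0.69) were also higher. Ugt2b, raised at the low dose, was lower at the high dose by log2 -1.51, followed by Cyp2e1 (-0.99), Egf (-0.81), the hepatocyte growth factor gene Hgf (-0.42) and Timp3, an inhibitor of metalloproteinases (-0.41). In all, 18 of 231 genes differed, 11 higher and 7 lower at the high dose. Against retinoic acid, the high dose gave 34.8-fold more CYP2B1/2 (5.12) and more Cyp3a23-3a1 (2.84), UGT1A1 (1.12), UGT1A2 (0.94) and Lama3 (0.67). Ugt2b (-1.47), Cyp2e1 (-1.04), Cyp3a9 (-0.82), Col5a2 (-0.66) and Junb (-0.61) were lower with EMD 82571 than with retinoic acid. In all, 31 of 232 genes differed between the compounds, 15 higher and 16 lower, or 60 when the retinoic acid arrays were limited to the array batch of the EMD 82571 arrays, where CYP2B1/2 differed by 4.87 and Cyp3a23-3a1 by 3.12. Without replicate 1 or replicate 2 of the high-dose group, 16 or 17 genes differed between the compounds and Junb no longer passed, nor did it without replicate 2 or replicate 3 of retinoic acid, and Acta2 no longer differed between the doses without replicate 1 of either dose.

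**Figure D2:**
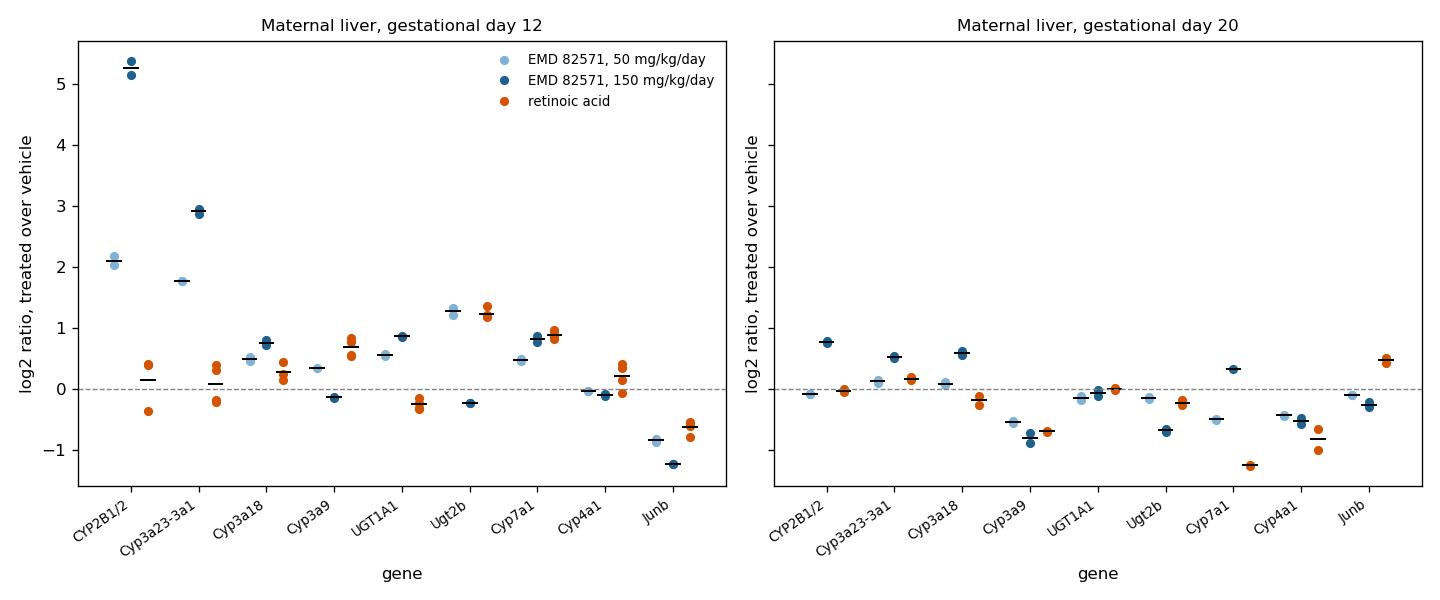
Log2 ratio of treated over vehicle for 9 genes in maternal liver on days 12 and 20, with a point per array and a bar at the group mean. CYP2B1/2 averages 2.10 and 5.26 at the low and high dose of EMD 82571 on day 12, against 0.76 at the high dose on day 20.

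In maternal liver on day 20, the low dose of EMD 82571 lowered 4 P450 genes. Cyp17a1, a steroid hydroxylase, fell 1.71-fold (-0.77 ± 0.09, n = 2, adjusted p = 7.16e-06), Cyp3a9 fell 1.46-fold (-0.55 ± 0.10) and Cyp7a1 fell 1.42-fold (-0.50 ± 0.08). Foxa3 (-0.46), Cyp4a1, a fatty acid hydroxylase (-0.44), and Bmp7, a bone morphogenetic protein (-0.29), were also lower. Actb, cytoskeletal actin (0.39 ± 0.04), Hyou1, a chaperone of the endoplasmic reticulum (0.33), Tgfb1 (0.31), the lipoprotein receptor Lrp1 (0.25) and Rarb (0.23) rose. CYP2B1/2 (-0.08) and Cyp3a23-3a1 (0.12) did not pass. Of 8 genes of hepatocyte function, 3 fell and none rose, also when adjusted over the list alone, with no list call (camera adjusted p = 0.241). In all, 24 of 238 genes passed, 9 higher and 15 lower. The count was 6 without replicate 1 and 9 without replicate 2, when Hyou1, Rarb, Foxa3 and Cyp4a1 no longer passed, nor did Tgfb1 without replicate 1 or Lrp1 without replicate 2.

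The high dose on day 20 raised some P450 genes in maternal liver and lowered others. CYP2B1/2 rose 1.7-fold (0.76 ± 0.12, n = 2, adjusted p = 0.000379), Cyp3a18 rose 1.5-fold (0.59 ± 0.09) and Cyp3a23-3a1 rose 1.43-fold (0.52 ± 0.11). Cyp3a9 fell 1.75-fold (-0.81 ± 0.10) and Ugt2b fell 1.61-fold (-0.69 ± 0.05). Cyp4a1 (-0.53), Cyp17a1 (-0.48), Bmp7 (-0.20) and Serpina1, the antiprotease alpha-1-antitrypsin (-0.40, but 0.0408 with the gene mean over groups subtracted), were lower. That mean takes in the fall of Serpina1 in embryo bone (-3.06 at the high dose), so the turn does not show a dye effect. Lama3 (0.25), Egfr (0.21) and Actb (0.17) rose, while Rarg, a retinoic acid receptor (-0.25), Hgf (-0.21) and the collagen Col18a1 (-0.26 and -0.18 by its 2 probes) fell. Of 20 phase I genes, 3 rose and 2 fell, or 5 and 2 when adjusted over the list alone, with no list call (camera adjusted p = 0.419). In all, 17 of 239 genes passed, 6 higher and 11 lower. The count was 4 without replicate 1 and 8 without replicate 2, when Cyp3a23-3a1, Lama3, Egfr, Actb, Serpina1, Bmp7 and Col18a1 no longer passed, nor did Cyp4a1, Cyp17a1, Rarg and Hgf without replicate 1.

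In maternal liver on day 20 with retinoic acid, Cyp7a1 fell 2.39-fold (-1.26 ± 0.08, n = 2, adjusted p = 1.67e-10), Lama3 fell 1.83-fold (-0.87 ± 0.07), Cyp4a1 fell 1.78-fold (-0.83 ± 0.09) and Fmo5, a flavin monooxygenase, fell 1.66-fold (-0.73 ± 0.09). Cyp3a9 (-0.70), Cyp17a1 (-0.56), Bmp7 (-0.18) and the constitutive chaperone Hspa8 (-0.55) were also lower. A2m, an acute-phase protein of the rat, rose 2.3-fold (1.2 ± 0.37, adjusted p = 0.0267). Its wide error is pooled over all groups and is not the spread of these arrays. Ppard, a fatty acid receptor (0.65), Pdgfa (0.55), the laminin chain Lama2 (0.49), Junb (0.47), Jun (0.42), E-cadherin Cdh1 (0.42), the chaperone Hspa5 (0.33) and Rarb (0.20) rose. Hspa5 stood at -0.15 in the fit of the median-centred deposited log2 ratios. Of 29 genes of the list of extracellular matrix and remodelling, 4 rose and 3 fell, or 5 and 3 when adjusted over the list alone, and of 19 phase I genes 1 rose and 3 fell, also when adjusted over the list alone. The matrix list had a median of -0.01, a mean of 0.02 and an upward test direction. In all, 46 of 229 genes passed, 22 higher and 24 lower. The count was 15 without either array, when A2m, Lama2, Junb, Cdh1, Jun, Hspa5 and Rarb no longer passed, nor did Bmp7 without replicate 2.

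High against low dose in maternal liver on day 20, 8 of 238 genes differed. CYP2B1/2 (0.85), Cyp7a1 (0.83), Cyp3a18 (0.50), Pdgfa (0.39) and Lama3 (0.38) were higher at the high dose, and Ugt2b (-0.53), Tgfb1 (-0.36) and Actb (-0.22) were lower. Set against retinoic acid, the high dose had more Cyp7a1 (1.59), Lama3 (1.12) and Fmo5 (0.80). CYP2B1/2 and Cyp3a18 passed as higher too, with the treated channel below background on the retinoic acid arrays, so no value is given. Junb (-0.73), Serpina1 (-0.65), Ppard (-0.60), Pdgfa (-0.50) and Ugt2b (-0.46) were lower than with retinoic acid, among 18 of 229 genes, 9 in each direction. The retinoic acid arrays lie in another array batch, so the compound and the batch cannot be told apart in this comparison. The dose count was 2 without replicate 1 of the low dose, replicate 2 of the low dose or replicate 2 of the high dose, and 1 without replicate 1 of the high dose, and CYP2B1/2, Cyp3a18, Pdgfa, Lama3, Tgfb1 and Actb no longer passed in any of these. The compound count was 8 without replicate 1 of the high dose and 10 without replicate 1 of retinoic acid; Junb and Ppard failed without each of the 4 arrays, Serpina1 without replicate 1 of either group, and CYP2B1/2 without replicate 1 of the high dose.

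In the day-12 embryo, the low dose of EMD 82571 moved genes by small amounts. Flt4, a vascular endothelial growth factor receptor of lymphatic vessels, rose 1.27-fold (0.35 ± 0.07, n = 2, adjusted p = 0.00101), and the chaperone gene Hspa4 rose 1.2-fold (0.26 ± 0.04, adjusted p = 0.000114). The Wnt receptor Fzd3 (0.32), the laminin chain Lamc1 (0.27) and Met, the receptor of hepatocyte growth factor (0.24), rose as well. Cyp2c12, a P450 of female rat liver, fell by 0.57 on the log2 scale and the glucuronosyltransferase UGT1A7 fell by 0.49. UGT1A2, Cyp4a1 and Ugt2b passed as lower but lay below background in both channels, so no fold is given for them. Of 17 phase I genes 4 fell, of 8 phase II genes 3 fell and of 8 hepatocyte genes 2 fell, with none rising, or 4, 4 and 3 when adjusted over the list alone and none of these lists called. Over the 35 probes at least 4-fold brighter in maternal liver than in embryo, the log2 ratio fell with the maternal liver level (Spearman rho = -0.38 across genes, permutation p = 0.0243, adjusted p = 0.0486 over 10 such relations), where genes are not independent replicates. In all, 33 of 219 genes passed, 9 higher and 24 lower, and 13 of the lower genes were not above background in both channels on each array. The count was 15 without replicate 1 and 10 without replicate 2, when Fzd3, Lamc1, Cyp2c12 and UGT1A7 no longer passed, nor did Met without replicate 2, and a limma fit of the day-12 embryo arrays alone called 0 genes, with 31 at an unadjusted p under 0.05.

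At the high dose, the day-12 embryo showed small changes. Rps7, a ribosomal protein gene, rose 1.21-fold (0.27 ± 0.05, n = 2, adjusted p = 0.00151). Flt4 (0.25), the metalloproteinase inhibitor Timp1 (0.22), Hspa4 (0.22 ± 0.04) and Bmp7 (0.16) rose as well. Flt4 stood at -0.0848 in the fit of the median-centred deposited log2 ratios. Cyp2d2 (-0.52 ± 0.10), Serpina1 (-0.45 ± 0.11) and Ugt2b (-0.32), all known for high expression in liver, fell. Col1a2, a chain of type I collagen (-0.52 ± 0.10), Col5a2 (-0.35 ± 0.05, adjusted p = 3.74e-05), the protease Plau (-0.43), Foxj1, a transcription factor of ciliated cells (-0.43), and the integrin Itgb6 (-0.29) were also lower. Of 8 genes of the list of heat shock and unfolded protein response, 1 rose over all genes and 3 rose when adjusted over the list alone, and the list moved up (camera adjusted p = 0.0015), a call that held with an estimated correlation (adjusted p = 0.000828). Beside Hspa4, its members Hspa5 (0.23), Hyou1 (0.21) and Hspa8 (0.16) did not pass over all genes. Of 30 matrix genes, 1 rose and 3 fell, or 1 and 4 when adjusted over the list alone, without a list call. Over the 39 probes at least 4-fold brighter in maternal liver, the ratio fell with the maternal liver level (rho = -0.49 across genes, permutation p = 0.00161, adjusted p = 0.00537). In all, 16 of 232 genes passed, 5 higher and 11 lower. The count was 10 without replicate 1 and 15 without replicate 2, when Flt4, Serpina1 and Foxj1 no longer passed, nor did Bmp7, Plau and Itgb6 without replicate 1 or Rps7 and Timp1 without replicate 2, and a limma fit of the day-12 embryo arrays alone called 0 genes, with 23 at an unadjusted p under 0.05.

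With retinoic acid, the day-12 embryo arrays fell into 2 sets that differed by array batch. Serpina1 rose 1.92-fold (0.94 ± 0.08, n = 4, adjusted p = 6.67e-09) and Cyp2d2 rose 1.54-fold (0.62 ± 0.07). Dcn (0.76 ± 0.15) and Pold3, a DNA polymerase subunit (0.27), rose and Col15a1 (-0.44 ± 0.09) fell in the mean of all 4 arrays, which joins 1.43, 0.51 and -0.85 in array batch A with 0.08, 0.03 and -0.03, none passing, in array batch B. Rps7 (0.27), Timp1 (0.27), Timp3 (0.18), Bmp5 (0.17), Tgfb1 (0.15) and Bmp7 (0.09, but -0.00917 with the gene mean over groups subtracted) rose by smaller amounts. Foxj1 (-0.39), the steroid hydroxylase Cyp17a1 (-0.37) and Cyp1a1 (-0.17) fell. Serpina1 (1.22 and 0.66), Rps7 (0.36 and 0.17) and Cyp17a1 (-0.22 and -0.52) passed in array batches A and B at unlike sizes. Of the genes above, Tgfb1, Bmp5 and Foxj1 passed in array batch A alone (0.28, 0.25 and -0.62 against 0.03, 0.09 and -0.16) and Cyp1a1 in array batch B alone (-0.28 against -0.07). Csf2, a myeloid growth factor, and UGT1A4 passed as lower with the treated channel below background on each array and the vehicle channel above it on 1, so no fold is given. Of 8 genes of hepatocyte function, 5 rose and 1 fell, or 6 and 1 when adjusted over the list alone, among them the liver transcription factors Hnf4a (0.59) and Cebpb (0.46) against Cyp7a1 (-0.20). The list moved up (camera adjusted p = 0.0325), a call lost at adjusted p = 0.338 with an estimated correlation, at 0.118 without replicate 1 and at 0.13 without replicate 2, and in array batch B alone Hnf4a stood at -0.0149 and Cebpb at -0.0796. Of the 5 genes of the list of retinoid metabolism and response 1 fell, also when adjusted over the list alone (camera adjusted p = 0.912, direction down, median 0.02), and Crabp2, a retinoic acid binding protein (0.05), and Rarb (0.02) did not pass.

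In all, 79 of 232 genes passed in the day-12 embryo with retinoic acid, 38 higher and 41 lower. Ratios correlated across genes with r = 0.959 within array batch A and 0.80 within array batch B, but with r from -0.203 to -0.166 between the batches. Array batch A alone gave 126 genes and array batch B alone 86, and among 225 genes measured in both, 19 passed in the same direction in each batch while 30 passed in opposite directions. Over the probes at least 4-fold brighter in maternal liver, the ratio rose with the maternal liver level in array batch B (16 above 0 and 22 below, rho = 0.62 across 38 genes, permutation p = 4e-05, adjusted p = 0.0002), and the relation did not pass in array batch A (rho = -0.15 across 37 genes, permutation p = 0.383, adjusted p = 0.478). The pooled values are therefore means of unlike sets. The count was 48 without replicate 2, when Bmp5, Tgfb1, Cyp1a1, Bmp7 and Cebpb no longer passed, Bmp5, Tgfb1, Bmp7 and Cebpb failed without replicate 1, Cyp1a1 and Cyp7a1 failed without replicate 3 or replicate 4, Bmp7 failed without replicate 4, and a fit of the day-12 embryo arrays alone called 2 genes.

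**Figure D3:**
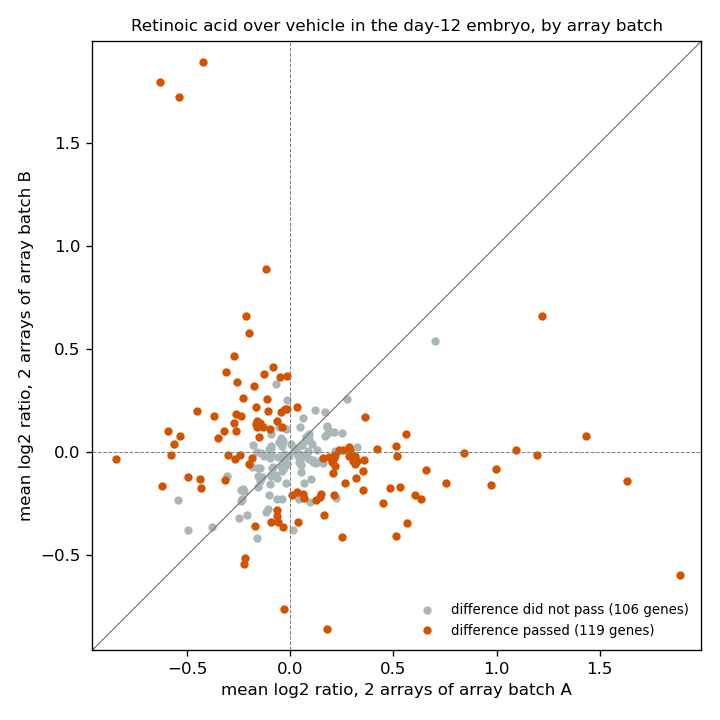
Mean log2 ratio of retinoic acid over vehicle in the day-12 embryo for 225 genes, with the 2 arrays of array batch A on the horizontal and the 2 of array batch B on the vertical axis. The 119 genes whose difference between the batches passed are orange, and most of them lie away from the diagonal of equal ratios.

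Between the doses in the day-12 embryo, 2 of 219 genes differed, both higher at the high dose. They were Rps7 (0.36) and UGT1A2, for which no fold is given because at the low dose it lay below background in both channels. Of 26 matrix genes none passed over all genes or when adjusted over the list alone (limma, 23 of all 219 genes at an unadjusted p under 0.05), yet the list moved down at the high dose (camera adjusted p = 0.00306), a call lost at adjusted p = 0.0778 with an estimated correlation and at 0.306 without replicate 2 of the high dose. Its members with the smallest p were Plau, with the vehicle channel below background at the low dose, Col4a2 (-0.21), Timp4 (-0.28) and Mmp2 (-0.26). The count was 8 without replicate 1 of the low dose and 1 without replicate 2 of the low dose, when Rps7 no longer passed, nor did it without replicate 2 of the high dose.

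Against retinoic acid in the day-12 embryo, the high dose was lower for Dcn (-1.42), Cyp2c7 (-1.40), Serpina1 (-1.39 ± 0.14), Cyp2d2 (-1.15) and Hnf4a (-0.97), and higher for Hyou1 (0.37). These pool unlike batches of retinoic acid arrays, and against array batch A alone, which holds the EMD 82571 arrays, the differences were -2.09, -0.27, -1.66, -1.23, -1.58 and 0.37 in that order. UGT1A2 and Csf2 passed as higher near background, so no value is given. Of 8 hepatocyte genes 3 were lower, or 5 when adjusted over the list alone, including Foxa3 (-0.62) (camera adjusted p = 0.00505), a call lost at adjusted p = 0.12 with an estimated correlation. Of 30 matrix genes 4 were lower, also when adjusted over the list alone, namely Plau (-0.52), Col5a2 (-0.49), the collagen chaperone Serpinh1 (-0.32) and Col4a2 (-0.19). That list moved down (camera adjusted p = 0.0396), a call lost at adjusted p = 0.279 with an estimated correlation and without any of 5 arrays, at 0.326 without replicate 2 of the high dose from 0.0507 to 0.136 without the retinoic acid arrays in turn, and at 0.416 against array batch A alone. In all, 26 of 232 genes differed, 8 higher and 18 lower, and 84 differed against array batch A alone. The count was 9 without replicate 1 of the high dose and 12 without replicate 2, when Hyou1, Cyp2c7, Serpinh1 and Col4a2 no longer passed, nor did UGT1A2, Plau and Foxa3 without replicate 1 or Hnf4a without replicate 2. Among the retinoic acid arrays, leaving out replicate 1 or 2 ended the call for Plau, replicate 1 or 4 that for Col4a2, and replicate 3 or 4 that for Cyp2c7.

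In embryo liver on day 20, a cartilage collagen gene and chaperone genes were higher than vehicle at the low dose of EMD 82571. The cartilage gene Col2a1 was measured in array batch C alone, so it has no value with retinoic acid in this tissue. The cause of its rise was not tested at either dose. Col2a1, the main collagen of cartilage, rose 1.46-fold (0.55 ± 0.07, n = 2, adjusted p = 0.000404), Hsph1, a heat shock protein, rose 1.37-fold (0.45 ± 0.06), and Hyou1 (0.35), Hspa8 (0.32), the DNA polymerase gene Pold1 (0.32) and Bmp7 (0.13) rose. Acta2 fell 1.53-fold (-0.61 ± 0.14), Sult1b1, a sulfotransferase, fell 1.47-fold (-0.56 ± 0.10), and Col1a2 (-0.44), Cyp17a1 (-0.42), Cdh1 (-0.36) and Bmp4 (-0.29) fell. Of 10 genes of heat shock and unfolded protein response, 3 rose and 1 fell, or 5 and 1 when adjusted over the list alone, with no list call (camera adjusted p = 0.0939). In all, 30 of 239 genes passed, 13 higher and 17 lower. The count was 10 without replicate 1 and 7 without replicate 2, when Hyou1, Col1a2, Cdh1, Bmp4 and Bmp7 no longer passed, nor did Sult1b1 without replicate 1 or Hspa8, Acta2 and Cyp17a1 without replicate 2.

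The high dose changed 92 of 238 genes in embryo liver, 44 higher and 48 lower. Col2a1 rose 4.12-fold (2.04 ± 0.07, n = 2, adjusted p = 1.18e-09), with Col9a3, another cartilage collagen (0.65), Foxj1 (0.75 ± 0.12), Junb (0.70 ± 0.15), the chaperone Hsp90aa1 (0.69 ± 0.10), Plcg1, a phospholipase of growth factor signalling (0.64), Bmp7 (0.58 ± 0.04) and Ppp1r15a, a stress-induced phosphatase subunit (0.53). The glucuronosyltransferase UGT2B6 fell 2.26-fold (-1.18 ± 0.15), Egfr 1.99-fold (-1.0 ± 0.06, adjusted p = 4.38e-12) and Cyp7a1 1.98-fold (-0.99 ± 0.08), and Sult1b1 fell by log2 0.82. The growth factor Igf1 (-0.78 ± 0.10), Ugt2b15 (-0.65), the proteoglycan Sdc2 (-0.64), UGT1A6 (-0.58), Tgfb1 (-0.39) and Bmp4 (-0.20) also fell, whereas Cyp3a23-3a1 rose (0.41). Of 10 bone and cartilage genes 3 rose and 1 fell, of 31 matrix genes 9 fell, of 20 phase I genes 1 rose and 5 fell, of 8 hepatocyte genes 1 rose and 3 fell, and of 22 growth factors and receptors 2 rose and 5 fell. Of 5 genes of the list of calcium and cyclic nucleotide signalling 3 rose, and of 10 heat shock genes 4 rose and 1 fell. All these counts were the same when adjusted over the list alone, and no list was called (camera adjusted p from 0.104 to 0.575). The count was 55 without replicate 1, and without replicate 1 or replicate 2 respectively Cyp3a23-3a1 or Sdc2 no longer passed, with Bmp4 failing in both.

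Retinoic acid changed 115 of 228 genes in embryo liver on day 20, 46 higher and 69 lower. Cyp2e1 rose 2.09-fold (1.06 ± 0.14, n = 2, adjusted p = 3.73e-06), Flt4 rose 1.53-fold (0.61 ± 0.07), and Tgfb1 (0.57 ± 0.06), fibronectin Fn1 (0.57), the proteoglycan Bgn (0.57), the retinoid X receptor Rxra (0.52), the liver BMP ligand Gdf2 (0.51) and the integrin Itga5 (0.48) rose. Rarb was at least 1.12-fold higher, with the vehicle channel below background. L1cam, a neural adhesion molecule, was at least 1.5-fold lower, with the treated channel below background, and Cyp1a1 (-0.48), Bmp4 (-0.41) and Cyp3a23-3a1 (-0.30) fell. UGT2B6 fell near the background (-0.59). Acan, the cartilage proteoglycan, and the transcription factor Foxc2 passed as lower with the treated channel below background on both arrays and the vehicle channel above it on 1, so no fold is given, and Csf3, Pdgfb and Fgf5 passed as lower with both channels below it. Of 30 matrix genes 8 rose and 5 fell, of 21 growth factors and receptors 7 rose and 4 fell, and of 8 bone and cartilage genes 1 rose and 4 fell, all also when adjusted over the list alone. Of 19 phase I genes 2 rose and 8 fell, or 2 and 9 when adjusted over the list alone, and no list was called. Of the 22 genes with neither channel above background 16 passed, all lower, against 65 of the 148 above background in both channels on each array, 38 higher and 27 lower. The count was 65 without replicate 1 and 70 without replicate 2, with Cyp3a23-3a1 failing in both, Pdgfb, Rarb and Bmp4 without replicate 1 and UGT2B6 without replicate 2.

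**Figure D4:**
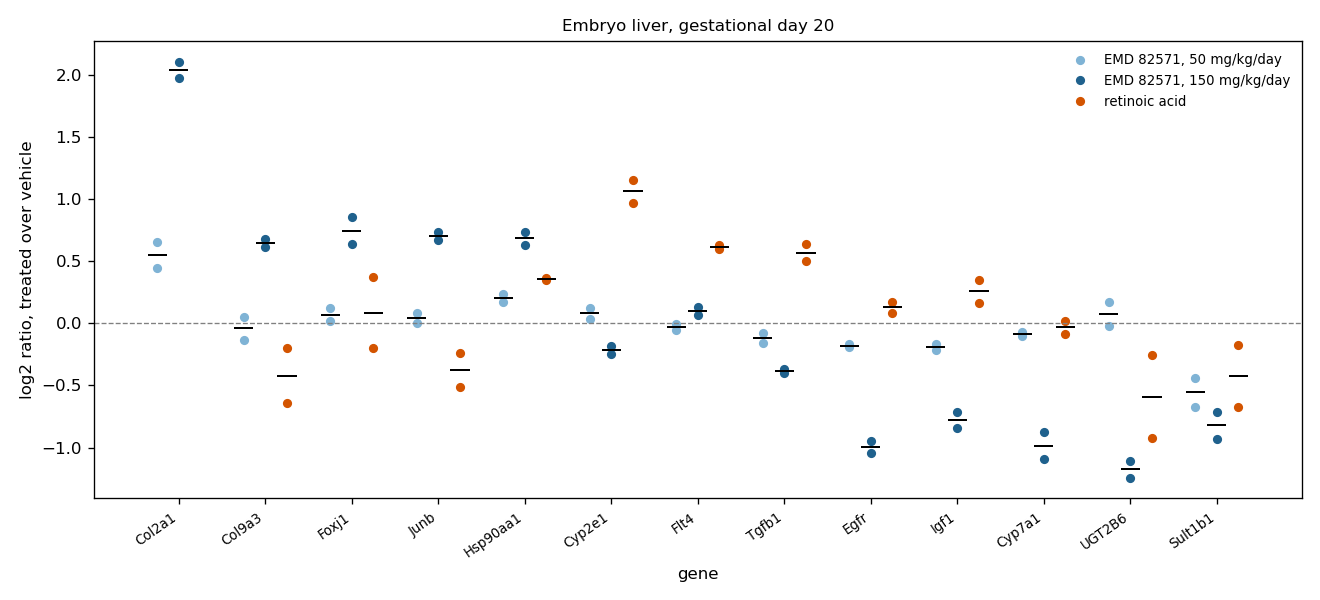
Log2 ratio of treated over vehicle for 13 genes in embryo liver on day 20, with a point per array and a bar at the group mean. Col2a1 averages 0.55 and 2.04 at the low and high dose of EMD 82571, and Cyp2e1 averages 1.06 with retinoic acid.

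Dose mattered for 26 of 238 genes in embryo liver, 15 higher and 11 lower at the high dose. Col2a1 (1.49), Col9a3 (0.69), Foxj1 (0.68), Junb (0.66) and the gap junction gene Gja1 (0.56 and 0.40 by its 2 probes) were higher, and UGT2B6 (-1.25), Cyp7a1 (-0.90), Egfr (-0.82), Ugt2b15 (-0.69) and UGT1A6 (-0.60) were lower. Without replicates 1 and 2 of the low dose in turn 17 and 15 genes differed, and without those of the high dose 14 and 17. Junb failed without each of these arrays, Foxj1 and Col9a3 failed without replicate 1 of the high dose, Foxj1 failed also without replicate 1 and Col9a3 without replicate 2 of the low dose, and Ugt2b15 failed without replicate 1 of the high dose.

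The compounds differed for 94 of 227 genes in embryo liver, 53 higher and 41 lower with EMD 82571. Junb (1.08), Col9a3 (1.07) and Ddit3, a stress-induced transcription factor (0.79), were higher with EMD 82571, as was Acan, with no value since its treated channel lay below background with retinoic acid, while Cyp2e1 (-1.28), Egfr (-1.12), Igf1 (-1.04), UGT1A6 (-1.01) and Tgfb1 (-0.96) were lower. Of 30 matrix genes 1 was higher and 11 were lower, also when adjusted over the list alone, among them Lamc1 (-0.67), tenascin Tnc (-0.50), Col4a2 (-0.47) and the metalloproteinase Mmp2, whose vehicle channel lay below background with retinoic acid. The list moved down (camera adjusted p = 0.0197), a call lost at adjusted p = 0.139 with an estimated correlation and at 0.0584 without replicate 2 of retinoic acid. The retinoic acid arrays lie in another array batch, so compound and batch cannot be told apart here. Ddit3 passed without replicate 2 of retinoic acid but not without any of the other 3 arrays.

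In embryo bone on day 20, 5 cartilage genes rose at the low dose of EMD 82571, of which Hapln1 and Col9a3 are on none of the gene lists. Col11a1, a cartilage collagen on the list of bone and cartilage genes, did not pass as higher at either dose. Col9a1 rose 2.47-fold (1.31 ± 0.12, n = 2, adjusted p = 3.67e-08), Col2a1 2.37-fold (1.25 ± 0.07), the cartilage link protein gene Hapln1 2.29-fold (1.2 ± 0.07, adjusted p = 7.68e-12), Col9a3 2.22-fold (1.15 ± 0.11) and Acan 1.74-fold (0.80 ± 0.07). Serpina1 fell 6.92-fold (-2.79 ± 0.11, adjusted p = 1.38e-15) and A2m fell 2.89-fold (-1.53 ± 0.37, adjusted p = 0.00487), as did Cyp2d2 (-0.71). Mmp9, the gelatinase of osteoclasts (-0.54), Itgb3, an osteoclast integrin (-0.49), Spp1, the bone matrix protein osteopontin (-0.35), and Tgfb1 (-0.30) fell, and Bmp7 rose (0.15). Of 10 bone and cartilage genes 3 rose and 2 fell, of 5 genes of the list of morphogen signalling and patterning 2 rose, of 31 matrix genes 4 fell and of 15 genes of cell adhesion and integrins 3 fell, all also when adjusted over the list alone and with no list called. In all, 29 of 238 genes passed, 12 higher and 17 lower. The count was 16 without replicate 1 and 14 without replicate 2, when A2m and Itgb3 no longer passed, nor did Tgfb1 and Bmp7 without replicate 1 or Spp1 without replicate 2.

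At the high dose the same 5 genes were higher in embryo bone, Col9a1 on the 1 array that measured it. For none of those measured on both arrays did the difference between the doses pass. Col2a1 rose 2.87-fold (1.52 ± 0.07, n = 2, adjusted p = 1.06e-08), Col9a3 2.75-fold (1.46 ± 0.11) and Hapln1 2.17-fold (1.12 ± 0.07), while Col9a1 (1.72) was measured on 1 array. Acan, added after its values were seen, rose by 0.79 ± 0.07. Foxj1 rose 3-fold (1.59 ± 0.12, adjusted p = 1.16e-09), Hoxa2, a patterning gene, rose 2.51-fold (1.33 ± 0.09), and Pparg, the adipocyte receptor (0.83), Vegfa (0.80), Crabp2 (0.54) and Bmp7 (0.48 ± 0.04) rose. Serpina1 fell 8.36-fold (-3.06 ± 0.11, adjusted p = 1.82e-16), A2m fell 2.67-fold (-1.42 ± 0.37, adjusted p = 0.00464) and Mmp9 fell 2.15-fold (-1.10 ± 0.10). BMP8 (-0.94), Itgb3 (-0.93 ± 0.12), Cyp2d2 (-0.82) and Tgfb1 (-0.77 ± 0.06) fell, and Col1a2 was lower on the 1 array that measured it (-1.02). Of 10 bone and cartilage genes 3 rose and 3 fell (camera adjusted p = 0.906), of 31 matrix genes 5 rose and 9 fell, and of 5 morphogen genes 4 rose and 1 fell, all also when adjusted over the list alone. Of 8 hepatocyte genes 2 rose and 2 fell, also when adjusted over the list alone, with a median of -0.02 and a mean of -0.46. In all, 74 of 238 genes passed, 40 higher and 34 lower. The count was 36 without replicate 1 and 34 without replicate 2, when Vegfa and Crabp2 no longer passed, nor did Pparg and A2m without replicate 1.

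With retinoic acid, some liver genes were higher in embryo bone on day 20. Cyp2c7, a liver P450, was at least 5.06-fold higher (adjusted p = 2.08e-06, n = 2), with the vehicle channel below background, A2m rose 4.39-fold (2.13 ± 0.37) and HSST, a hydroxysteroid sulfotransferase, rose 2.7-fold (1.43 ± 0.37). Cyp2d2, CYP2A1/2 and Cyp2e1 were at least 1.57-fold, 1.29-fold and 1.22-fold higher. In the fit of the median-centred deposited log2 ratios, however, Cyp2d2 (-0.0596), CYP2A1/2 (-0.0606), Cyp2e1 (-0.0848) and Cyp2c12 (-0.11) lay below 0. Cyp2c12 (0.70 in the ratios used here), the epithelial collagen Col17a1 (0.62), Bmp2 (0.27) and Bmp7 (0.18) rose. Mmp24, a membrane metalloproteinase, fell 3.4-fold (-1.77 ± 0.08, adjusted p = 1.06e-08), L1cam fell 2.55-fold (-1.35 ± 0.10), and Plcb1, a phospholipase (-1.36), Csf2 (-1.22) and Col2a1 (-0.30, but 0.0281 with median centring) fell. Cyp3a23-3a1 was lower on the 1 array that measured it (-0.99), and Cyp1a1, CYP2B1/2, Csf3 and Cyp2c11 passed as lower with both channels below background. Of 30 matrix genes 8 rose and 5 fell, also when adjusted over the list alone, with the basement membrane genes Col4a1 (0.48), Lamb1 (0.44) and Col4a2 (0.30) up. That list moved up (camera adjusted p = 0.0246), a call lost at adjusted p = 0.2 with an estimated correlation and at 0.26 without replicate 2. Of 20 phase I genes 6 rose and 10 fell, and of 8 phase II genes 1 rose and 6 fell, also when adjusted over the list alone and without a list call.

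Of the 29 probes at least 4-fold brighter in maternal liver than in embryo bone, 9 lay above 0 and 20 below (4 and 5 of the 9 above background in both channels on both arrays), and the ratio with retinoic acid rose with the maternal liver level (rho = 0.72 across genes, adjusted p = 0.0002, with the unadjusted 2e-05 the smallest that the permutations can give). The relation was not past the threshold in embryo bone with EMD 82571 (rho = -0.05 and -0.07 at the low and high dose, permutation p = 0.782 and 0.675, adjusted p = 0.782 and 0.75). It was positive in embryo liver with retinoic acid (rho = 0.68 over 14 genes, permutation p = 0.00916, adjusted p = 0.0229) and did not pass in embryo liver with the high dose (rho = -0.55 over 15 genes, permutation p = 0.0384, adjusted p = 0.0639) or the low dose of EMD 82571 (rho = 0.29 over 13 genes, permutation p = 0.344, adjusted p = 0.478). In all, 126 of 235 genes passed in embryo bone with retinoic acid, 44 higher and 82 lower, or 43 and 41 with only probes above background on each array. Of the 20 genes with neither channel above background 18 passed, all lower, against 62 of the 154 above background in both channels on each array, 35 higher and 27 lower. Bmp2 no longer passed without either array, Cyp2c12 without replicate 1 and Cyp2e1 without replicate 2.

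**Figure D5:**
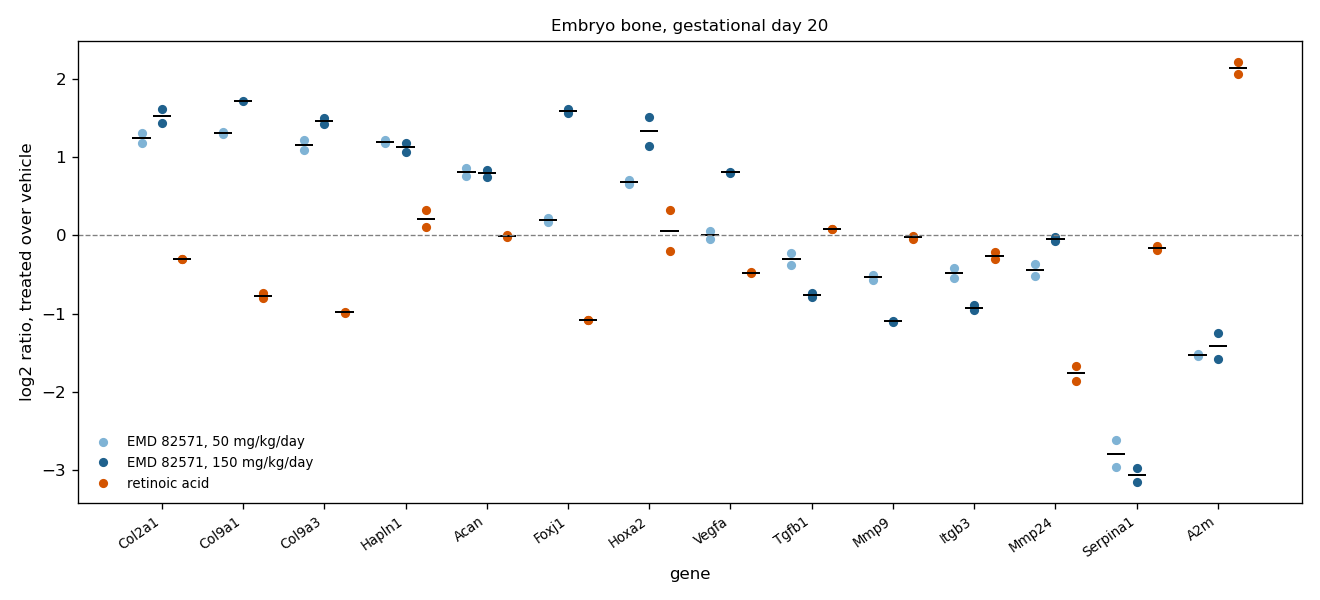
Log2 ratio of treated over vehicle for 14 genes in embryo bone on day 20, with a point per array and a bar at the group mean. Col2a1 averages 1.25 and 1.52 at the low and high dose of EMD 82571 and -0.30 with retinoic acid, and Serpina1 averages -2.79 and -3.06 with EMD 82571.

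Between the doses in embryo bone, 12 of 238 genes differed, 7 higher and 5 lower at the high dose. Foxj1 (1.39), Hoxa2 (0.65), L1cam (0.63), the protease Plat (0.43), Foxa1 (0.36) and Bmp7 (0.34) were higher. Mmp9 (-0.56), Tgfb1 (-0.46), Tnc (-0.41), the macrophage receptor Csf1r (-0.39) and Runx2, the master regulator of osteoblasts (-0.35), were lower. The count was 7 without replicate 1 and 2 without replicate 2 of the low dose, and 4 without replicate 1 of the high dose. Foxj1 and Plat passed without each array in turn, while Mmp9 and Runx2 failed without each of the 4, Tnc and L1cam without 3, Hoxa2, Foxa1 and Csf1r without replicate 2 of the low or replicate 1 of the high dose, and Tgfb1 and Bmp7 without replicate 2 of the low dose.

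Between the compounds, embryo bone differed most, with 150 of 234 genes past the threshold, 96 higher and 54 lower with EMD 82571. Foxj1 was 6.36-fold higher (2.67), and Col9a3 (2.44), Col2a1 (1.82) and Mmp24 (1.71) were higher. A2m was 11.7-fold lower (-3.55), and Serpina1 (-2.90) was lower. The differences of Col9a1 (2.49) and Col1a2 (-1.37) rest on 1 high-dose array each. Cyp2c7 and Cyp2d2 passed as lower too, with the vehicle channel below background on the retinoic acid arrays, so no value is given. Of 30 matrix genes 5 were higher and 12 lower, also when adjusted over the list alone, including Mmp9 (-1.07), Tnc (-0.80) and Col4a1 (-0.49). That list moved down (camera adjusted p = 0.0355), a call lost at adjusted p = 0.339 with an estimated correlation, and at 0.0523 and 0.0656 without replicates 1 and 2 of the high dose and 0.167 without replicate 2 of retinoic acid. The retinoic acid arrays are of the same array batch but form a session of their own, so compound and session cannot be told apart.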

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

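Tests of a trace of maternal liver RNA, of a higher cartilage share, of a single share of embryo liver RNA for both pairs of genes, of the array batches taken alone and of splits balanced by batch were chosen after the result was seen. In embryo bone with EMD 82571, cartilage genes rose (Col2a1 at log2 1.52 and Acan at 0.79 at the high dose) while Serpina1 (-3.06) and A2m (-1.42) fell. A larger share of cartilage in the treated bone would raise cartilage genes alike only if the rest of the bone lacked them and dim probes kept their full ratio. At the high dose the 5 cartilage markers, without Col11a1, which did not pass as higher, spanned a log2 range of 0.927 ± 0.183. Col9a1, the highest, was measured on 1 array. Of those measured on both arrays, Col2a1 exceeded Acan by 0.73 ± 0.10, both members of the list of bone and cartilage genes, and Hapln1 by 0.40 ± 0.10. Expression in the rest of the bone was not measured, and Acan and Hapln1 (mean log2 intensity 7.70 and 7.69) were dimmer than Col2a1 (10.04). These differences therefore leave the share open at that dose. At the low dose the share also stays open. The range of 0.503 ± 0.139 rests on Acan, added after its values were seen. The other 4 markers lay within 0.16 ± 0.16, with Col2a1 above Hapln1 by 0.05 ± 0.10. Embryo liver RNA in the vehicle channel would bring Serpina1 and A2m at a single share of their liver level. At the high dose, the only one tested in this way, the share was 5.23 times as high for Serpina1 as for A2m on 1 array and 10.3 times on the other. This argues against such RNA as the sole cause of both falls at that dose, if intensities are proportional to RNA. For A2m and Cyp2d2 a single share may account for the fall, with 1.11% and 1.08% on 1 array and 0.70% and 0.75% on the other (ratio 0.98 and 1.08), and for the liver markers as a set it stays open, since 11 liver markers had a median of -0.148 (95% interval -1.42 to 0.165). A response of bone cells to EMD 82571 was not tested and stays open.

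In embryo bone with retinoic acid, Cyp2c7 and A2m were higher, and 126 of 235 genes passed. Of these, 22 were at least 4-fold brighter in maternal liver and 104 were not. A trace of maternal liver RNA in the treated channel may account for the liver genes that rose, since the ratio rose with the maternal liver level (rho = 0.725 across 29 genes, and 0.778 across the 21 with signal in at least 1 channel on both arrays). Of these 21, however, 12 were not above background in both channels on both arrays, and dim probes ran low on these arrays. The relation therefore cannot tell such a trace from signal near background. Of the 29, 20 lay below 0, but only 9 of the 29 were above background in both channels on both arrays, 4 of them above 0 and 5 below, so the direction excludes nothing. Embryo liver RNA was left open by a median of -0.145 over 11 markers (95% interval -0.589 to 1.43). For the count, signal near background was also left open, since 43.5% of the probes above background on both arrays passed against 53.6% of all tested, which include them. Of the 154 probes above background in both channels on both arrays 62 passed, 35 higher and 27 lower. Of the 47 above it on part of the arrays or channels 39 passed, 5 higher and 34 lower. All 18 that passed of the 20 with neither channel above it were lower, so the excess of lower genes lay in the dim probes. A response to retinoic acid in bone was not tested and stays open, and the retinoic acid arrays form a session of their own.

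In the day-12 embryo with retinoic acid, the arrays of array batches A and B differed for 119 of 225 genes, 54 higher and 65 lower in batch B. In batch B the liver genes A2m (1.89), HSST (1.79) and Cyp2c7 (1.72) were high, while of 38 genes at least 4-fold brighter in maternal liver 16 lay above 0 and 22 below. A general effect of the batch would also appear in maternal liver, where 44 of 227 genes differed, and the correlation of the difference between the tissues was r = 0.125 (95% interval -0.00759 to 0.253, 220 genes), which leaves it open. Liver RNA in the treated channel of batch B was left open by a median of 0.0288 over 19 liver markers (95% interval -0.156 to 0.661). A trace of maternal liver RNA was also left open, with rho = 0.623 over 38 genes. It was 0.715 across the 24 with signal in at least 1 channel on both arrays, 13 of them above 0 and 11 below. The sample labels are the same in both batches, while the titles of the embryo arrays hold the number 20 in batch A and 6 in batch B beside RA, without a unit. Whether this is a dose is not stated, and a dose difference was not tested and stays open.

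The response was tested for differences between tissues and days, in each case at the low dose, the high dose and with retinoic acid. Between embryo and maternal liver on day 12, 23, 36 and 56 genes differed. Between embryo liver and maternal liver on day 20, 33, 73 and 63 differed. Between embryo bone and embryo liver, 24, 90 and 111 differed. Between embryo bone and maternal liver on day 20, 34, 63 and 100 differed. Between days 20 and 12 of maternal liver, 33, 29 and 48 differed. With retinoic acid, the embryo bone arrays are of array batch C and those of both livers on day 20 of batch B, so tissue and batch cannot be told apart. Day and batch cannot be told apart with EMD 82571, with batch A on day 12 and batch C on day 20. With retinoic acid, day 12 joins batches A and B and day 20 is of batch B, and within batch B 63 of 225 genes differed between the days. For retinoic acid on day 12, with 4 arrays a group, 2 of the 35 splits of the 8 arrays gave at least 56 genes, namely the real one and one with 59 that follows the array batch and so is not a chance split. Of the 18 splits with 2 arrays of each batch on either side the real one gave the most, and the split that exchanges the tissues in 1 batch gave 53. That split tests whether the tissue difference itself differs between the batches, and so is not a chance split. The other balanced splits gave at most 25, but 18 splits are too few for a share under 0.05, so chance stays open for the count. Array batch A alone gave 105 genes and batch B alone 74. Of 42 genes past the threshold in each, 18 differed in the same direction, such as Cyp7a1 (-0.89 and -1.28), and 24 in opposite directions.

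These counts fell without single arrays. At the low dose on day 12, the embryo differed from maternal liver in 10 and 11 genes without replicates 1 and 2 of maternal liver, and at the high dose in 22, 20, 18 and 15 without embryo replicates 1 and 2 and maternal liver replicates 1 and 2. At the low dose on day 20, the livers differed in 12, 18, 20 and 12 genes without maternal replicates 1 and 2 and embryo replicates 1 and 2, and embryo bone differed from maternal liver in 20 without maternal replicate 1 and from embryo liver in 13 without replicate 2 of either tissue. At the high dose, embryo bone differed from embryo liver in 57 genes without liver replicate 1 and in 58 and 54 without bone replicates 1 and 2, and the days of maternal liver differed in 14 and 15 without day-12 replicates 1 and 2 and in 15 and 19 without those of day 20. With retinoic acid, the livers on day 20 differed in 40 genes without embryo liver replicate 1 and in 36 and 35 without maternal replicates 1 and 2, and the days of maternal liver in 26 and 31 without day-20 replicates 1 and 2.

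Some genes passed in opposite directions in the tissues or days compared, and the widest difference of each comparison that had any is given here. CYP2B1/2 differed by log2 -2.52 between embryo (-0.42) and maternal liver (2.10) on day 12 at the low dose, and Ugt2b by -1.44 with retinoic acid (-0.21 and 1.23). Both embryo values rest on a vehicle channel below background on each array. Neither the size nor the direction of these embryo changes is therefore reliable, nor is the opposite direction to maternal liver. Between embryo liver and maternal liver on day 20, Bmp7 differed by 0.42 at the low dose (0.13 and -0.29), Egfr by -1.20 at the high dose (-1.0 and 0.21) and Fmo5 by 1.04 with retinoic acid (0.31 and -0.73). Between embryo bone and embryo liver, Foxa1 differed by 0.75 at the high dose (0.30 and -0.45) and Rxra by -1.24 with retinoic acid (-0.72 and 0.52). Between embryo bone and maternal liver, Tgfb1 differed by -0.62 at the low dose (-0.30 and 0.31), Bmp7 by 0.68 at the high dose (0.48 and -0.20) and Lama3 by 1.09 with retinoic acid (0.22 and -0.87). Between days 20 and 12 of maternal liver, Cyp7a1 differed by -0.97 at the low dose (-0.50 and 0.47) and by -2.14 with retinoic acid (-1.26 and 0.88), and Bmp7 by -0.35 at the high dose (-0.20 and 0.15). Rxra and Lama3 compare array batch C with batch B, and the 2 day differences with EMD 82571 compare batch C with batch A, so batch cannot be excluded for them, while Cyp7a1 with retinoic acid differed by -2.18 within batch B. Several of these calls failed without 1 array. Bmp7 at the high dose in maternal liver on either day, Bmp7 at the low dose in embryo liver, Egfr in maternal liver and CYP2B1/2 in the embryo failed without replicate 1 or 2. Tgfb1 failed in both tissues and Lama3 in embryo bone without replicate 1, and Fmo5 in embryo liver without replicate 2.

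Signal was also found at 6 grid positions on the arrays of a batch whose files label them as empty, and this signal enters no comparison. The median Cy5 signal over background was 5.96 at a position on all 14 arrays of array batch C and 17.5 at a position on all 8 of array batch B. In array batch A it was 5.56 at a position above background on 10 of 12 arrays, and 1.48, 2.39 and 5.43 at 3 positions above background on all 12. The 7 positions empty in each batch had medians from 1.10 to 1.14, with 0 arrays above background. All 6 are among the 11 positions where the batches disagree on the name, and other batches name a gene there, some at a like signal, with 6.27 and 7.61 against the 5.56, 1.49 in batch C against the 1.48 and 2.39 in batch C against the 2.39. The cause was not tested.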

How the results depend on the processing

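Tests with uneven spots kept, with the date session as a random block, and with only probes above background on each array compared were chosen after the result was seen. Over 13 alternative settings, 163 counts stayed within 1.5 times the reported count, 25 rose and 58 fell by more. Of 5372 values of named genes, 4740 kept their direction and their side of the threshold, 516 no longer passed, 92 newly passed and 24 changed sign as called. Of 2547 list tests, 2491 kept their call, 14 lost it and 42 gained one. Keeping uneven spots moved none of 25 counts. The deposited log2 ratios had array medians from -0.70 to 0.33 and correlated with the ratios used here with r from 0.35 to 0.954 over 232 probes. Signal over background was low in array batch B, with medians of 1.54 in the treated and 1.85 in the vehicle channel. For the changes given here, the cause was not tested.

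The deposited log2 ratios were centred on the median of each array before the fit. With them, genes past the threshold numbered 111 at the low dose, 53 at the high dose and 20 with retinoic acid in the day-12 embryo. There they gave 0 (limma, 21 at an unadjusted p under 0.05) between the doses and 5 between the compounds. Maternal liver on day 12 gave 17, 23, 20, 4 and 12 in that order. On day 20 it gave 3 at the low and 6 at the high dose, 1 between doses and 3 between compounds. Embryo liver gave 1, 38, 60, 4 and 37. Embryo bone gave 14 and 36 at the low and high dose, 4 between doses and 96 between compounds. Differences between tissues or days summed to 505 in place of 816.

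A fit of the arrays of the same tissue and day alone gave, in the day-12 embryo, 0 at the low dose (limma, 31 at an unadjusted p under 0.05), 0 at the high dose (23), 2 with retinoic acid, 0 between doses (7) and 4 between compounds. In the day-12 embryo, the variance of that fit includes the difference between the unlike array batches of retinoic acid. It gave 28 between doses in maternal liver on day 12, and on day 20 it gave 74, 74, 111, 22 and 72. It also gave 60 in embryo liver and 46 in embryo bone at the low dose, and 35 between doses in embryo bone.

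With array batch as a random block (correlation 0.389), the day-12 embryo gave 19 at the low dose, 31 with retinoic acid and 43 between compounds, and maternal liver gave 28 with retinoic acid. On day 20, maternal liver gave 8, 6 and 21 and 10 between compounds, embryo liver 11 and 57 at the low and high dose, and embryo bone 19 and 45 and 24 between doses. With the session as a random block (correlation 0.404), the day-12 embryo gave 41 with retinoic acid, 4 between doses and 42 between compounds, and maternal liver 42 with retinoic acid. On day 20, maternal liver gave 7, 6 and 27 and 10 between compounds, embryo liver 11 and 58, and embryo bone 17 and 43 and 25 between doses. A fit with a mean for each batch of the day-12 retinoic acid arrays gave 84 between compounds in the embryo and 60 in maternal liver. These are the comparisons with array batch A alone given above, not a separate check. Array batch A alone gave 126 in the embryo with retinoic acid.

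Median centring gave 72 at the low and 32 at the high dose, 1 between doses and 15 between compounds in the day-12 embryo, and 29 with retinoic acid and 3 between doses in maternal liver on day 20. No background subtraction gave 19 in the day-12 embryo at the low dose, and between doses 41 in embryo liver and 40 in embryo bone. No filter on dim probes gave 1 between doses in the day-12 embryo, 46 in embryo liver at the low dose and 27 between doses in embryo bone. Subtracting the gene mean over groups gave 21 in the embryo and 17 in embryo bone at the low dose and 11 in maternal liver on day 20 at the high dose. Only probes above background gave 1 between doses and 16 between compounds in the day-12 embryo.

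Values that turned with the median-centred deposited log2 ratios were, at the low dose in the day-12 embryo, Crabp2 (0.49), Cyp3a23-3a1 (-0.24) and Cyp1a1 (-0.30). There at the high dose Flt4 (-0.0848) turned, with UGT1A4 (-0.10) between compounds. The same ratios turned Hspa5 (-0.15) and Lama1 (0.10) in maternal liver on day 20 with retinoic acid, and Cyp2c12 (-0.11), Cyp2d2 (-0.0596), Cyp2e1 (-0.0848) and CYP2A1/2 (-0.0606) in embryo bone with retinoic acid, with Spp1 (-0.55) between compounds there. Median centring turned Spp1 in embryo liver with retinoic acid (-0.36) and in embryo bone between compounds (-0.41), and Col2a1 in embryo bone with retinoic acid (0.0281). Subtracting the gene mean turned Bmp7 in the embryo with retinoic acid (-0.00917), Cyp3a23-3a1 in maternal liver on day 12 with retinoic acid (-0.24), and at the high dose Serpina1 in maternal liver on day 20 (0.0408) and CYP2B1/2 in embryo bone (-0.33). That mean also holds treatment effects, such as Serpina1 in embryo bone at the high dose (-3.06). For CYP2B1/2 it holds the rises in maternal liver on day 12 (2.10 and 5.26), so these turns do not show a dye effect. With retinoic acid on day 12, array batch A alone turned Cyp3a23-3a1 (-0.21) and Cyp1a1 (0.17) in maternal liver, and batch B alone turned CYP2B1/2 (-0.37) there and Hnf4a (-0.0149) and Cebpb (-0.0796) in the embryo.

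Leaving out each array in turn, with the lone array left assumed to vary like the other groups, moved 42 of 78 counts by over 1.5 times, 41 of them down. Arrays of different groups could not be paired, because the labels do not link them. In the day-12 embryo counts ran from 10 to 15 at the low dose (reported 33), 10 to 15 at the high dose (16), 48 to 84 with retinoic acid (79), 1 to 8 between doses (2) and 9 to 36 between compounds (26). In maternal liver on day 12 they ran from 15 to 16, at 18 both times, 50 to 65, 12 to 16 and 16 to 34 in the same order, and on day 20 from 6 to 9, 4 to 8, at 15 both times, 1 to 2 and 8 to 14. Embryo liver ran from 7 to 10, 55 to 62, 65 to 70, 14 to 17 and 63 to 85. Embryo bone ran from 14 to 16, 34 to 36, 86 to 97, 2 to 9 and 115 to 124. Of 1679 gene values, 1404 stayed as called, 267 no longer passed and 8 newly passed.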

Other observations

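No test in this part was chosen after the result was seen. In maternal liver on day 12, Tgfb1, Bmp2, Bmp7 and Spp1 changed by small amounts in some groups. At the low dose, Tgfb1, a regulator of matrix and growth, fell by 0.24 ± 0.06 on the log2 scale (n = 2), and osteopontin Spp1 fell by 0.38 ± 0.08. At the high dose, Tgfb1 rose (0.18) with Bmp7 (0.15), while Bmp2 (-0.27) and Spp1 (-0.26) fell, and Cyp1a1, a P450 induced by dioxin-like compounds, was at least 1.22-fold higher, with the vehicle channel below background. With retinoic acid, Tgfb1 (0.20 ± 0.04, n = 4) and Bmp7 (0.10) rose and Bmp2 (-0.19) fell, the last passing in array batch B alone (-0.29 against -0.08). Without replicate 1 or 2, Tgfb1 no longer passed at the low dose (Spp1 failed without replicate 2), and none of Tgfb1, Bmp2, Spp1, Cyp1a1 and Bmp7 passed at the high dose. With retinoic acid, Bmp2 failed without replicate 3 or 4 and Bmp7 without replicate 3.

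Of 10 genes of TGF-beta and BMP signalling, 4 rose and 1 fell in maternal liver on day 12 at the high dose (camera adjusted p = 0.756), 3 rose and 2 fell in embryo liver at the high dose (0.523), and 4 rose and 1 fell in embryo bone with retinoic acid (0.185), all also when adjusted over the list alone. In embryo liver with retinoic acid, 3 of 5 genes of morphogen signalling and patterning fell (0.414) and 2 of 5 genes of retinoid metabolism and response rose (0.713), also when adjusted over the list alone. In embryo bone with retinoic acid, 3 of 5 genes of calcium and cyclic nucleotide signalling fell (0.3), and of 8 hepatocyte genes 1 rose and 4 fell (0.437), also when adjusted over the list alone. A lone outlying array was looked for in 44 values of the groups of 4 arrays with Dixon's ratio, and 0 passed.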
